A study of Mus musculus with 9 samples.

How the data were processed

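Messenger RNA of splenic CD4+ T cells was sequenced in 9 libraries, 3 per group, after 18 h with exosomes of ApoE-deficient BMDM, exosomes of wild-type BMDM, or PBS. Per the labels, RNA was extracted with a Qiagen RNeasy Mini kit and libraries were prepared with the Universal Plus mRNA-Seq kit. The values used here are whole-number counts per gene as deposited by the authors, with no normalization. Per the submitters' processing notes, reads were aligned with STAR 2.7.5c to the mouse genome build GRCm38. The counting tool, its strand setting and the gene annotation it used are not given in the sources used here. Gene symbols and coordinates were looked up by Ensembl identifier in the GENCODE M21 annotation, which uses the same build, and 55450 of 55536 identifiers had a symbol.

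Groups and replicate numbers came from the sample titles and treatment labels. The design text calls the replicates biological, but no label says that they came from separate mice, so p-values measure the spread between these cultures. Within each group the counts of 2 libraries differed by 5.02 to 9.08 in chi-square per degree of freedom, so no pair looked like 1 library deposited again.

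Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14684 genes holding at least 99.92% of the counts of every library. Library sizes were scaled by TMM, a model with the 3 groups and no covariate was fitted to all 9 libraries, and the groups were compared by the edgeR quasi-likelihood F test. It had 6 residual and 21.1 prior degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. CPM are counts relative to the TMM-scaled library size, and standard errors are those of the log2 fold change. Differences between exosome groups were tested directly, not inferred from the 2 comparisons with PBS.

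Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided, where at least 5 members were measured. That held for 36 of 38 lists, and p was adjusted over the lists and the 3 comparisons together. With an estimated correlation only the NF-kB list kept its call, against PBS in either exosome group. Lists with estimates below the preset lost theirs too. For EKO_exo against PBS these included T cell receptor and CD28 signalling (estimate 0.008) and Th1 genes (-0.009). For the NF-kB list (-0.013) the camera adjusted p itself rose from 1.79e-07 to 0.0417 in that comparison. Correlation between members alone therefore does not account for the lost calls. A call lost with an estimated correlation does not by itself show that the members vary together. Several lists share members, such as Cd274, Il2ra and Irf8. For no called list did the median, the mean and the test differ in sign. Among lists not called they differed against PBS for nuclear oxidative phosphorylation, type I interferon and neutrophil markers in EKO_exo, and for B cell, neutrophil and NK cell markers in WT_exo. Between the exosome groups they differed for 12 lists: Th1, Th2, regulatory T cells, glycolysis, tricarboxylic acid cycle, cholesterol efflux, unfolded protein response, interferon gamma, NF-kB, IL-2 and STAT5, macrophages and dendritic cells.

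Before the data were examined, the groups, the tests, the lists, the alternatives and the rule for named genes were fixed. Under that rule the text names the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM, groups that did not overlap, and a symbol that is not a clone or predicted name. It adds the 3 members with the smallest p of each list that was called or had at least 3 called members, and Apoe, Il2, Ifng, Il2ra, Mki67, Foxp3, Cd4, Irak1 and Traf6 in every comparison. Other genes named because a count was 5 or less, or because they moved against the name of a list, fall outside the rule and were chosen after their values were seen. They include Ccnd2, Eno3, Il21, Gpr83, Capg, Hadh, Nr1h2, Scarb1 and Parp14. Some genes that the rule would name are not reported here.

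The scripts were tested on simulated negative binomial counts drawn from the real means, dispersions and library sizes, 5 simulations per comparison of 14684 genes. At 5 CPM or more, 62.9% of genes changed by 1.25-fold, 86.9% by 1.5-fold, 98.7% by 2-fold and 100% by 3-fold were recovered for EKO_exo against PBS. For WT_exo against PBS these shares were 61.9%, 90.2%, 99.4% and 100%, and for EKO_exo against WT_exo 59.1%, 85.8%, 98.8% and 100%. False calls made up 5.34%, 5.36% and 4.96% of calls. The recovered shares and false calls hold for counts that follow the fitted negative binomial. In the data, genes at 0 against a higher expectation, described below, numbered 135 over all libraries, where that model gave 10.4. The ratio of variance to mean was 7.07 in EKO_exo, 4.79 in PBS and 4.6 in WT_exo. The simulations therefore do not measure the rate of false calls in these data. A list shifted by 1.25-fold was called in 5 of 5 simulations of each comparison. List p was adjusted there within a single comparison, whereas calls in the data were adjusted over the comparisons together. Over the 5 simulations of EKO_exo against WT_exo 1 unshifted list was called, and 0 in those of the other comparisons. Genes were drawn independently, whereas the estimated correlation in the data was 0.319 for the cell cycle list. The list test was therefore not tried on members that vary together, on shifts under 1.25-fold, or with the adjustment used for the calls.

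To show what shared PBS libraries give without an effect, 100 simulations drew all 9 libraries from common means. The plan had been to hold the PBS libraries as measured; drawing them too adds their chance error, and this departs from the plan.

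The spread fell with level: the median biological coefficient of variation was 56.7% among the lowest of 10 equal classes of genes by level, at a mean count of 9.8, and 3.5% among the highest. The median 95% interval of a log2 fold change at 5 CPM or more reached 0.155 to 0.156 to either side. Reads carried no molecular identifiers that the sources used here mention, so floors cover counting error only. A comparison of a single value of 3 against 3 libraries cannot reach an exact p below 0.1. Genes that share reads with pseudogenes or close copies are uncertain, among them Tpi1, Pkm, Tpt1, ribosomal protein genes, H2 genes and immunoglobulin genes, as are genes overlapping another on either strand.

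Alternatives were DESeq2 size factors, no filter, a filter at a mean of 5 CPM, the Wald test of DESeq2 1.42.0, limma-voom, robust estimation, fits to only the 2 groups compared, a prior count of 0.5, an estimated correlation, the replicate number as a block, and leaving out each library. Chosen after seeing the data were a fit without EKO_exo replicates 1 and 3, libraries thinned to the smallest total, and adjustment of list p-values within each comparison. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.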

Results

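RNA was measured by sequencing in 9 cultures of CD4+ T cells, the helper class of T lymphocytes, taken from the spleens of male wild-type mice aged 6 to 12 weeks. The cells were stimulated with beads carrying antibodies to CD3 and CD28, which engage the T cell receptor and its costimulatory receptor, together with 5 ng/mL of the growth factor IL-2. During the 18 h of stimulation 3 cultures received exosomes, small secreted vesicles, from wild-type BMDM (the usual abbreviation for bone marrow-derived macrophages), named WT_exo here. Another 3 received exosomes from BMDM of mice lacking apolipoprotein E (EKO_exo), and 3 received phosphate-buffered saline without exosomes (PBS). The exosome dose was 2e+09 particles per mL. The total count was 28279741, 25792975 and 30221565 in EKO_exo replicates 1, 2 and 3. It was 28412418, 29298161 and 30464334 in PBS and 30922654, 29138950 and 32971791 in WT_exo. The mitochondrial share of counts was 2.35 ± 0.03% in PBS, 2.24 ± 0.08% in WT_exo and 2.28 ± 0.07% in EKO_exo (SD, n = 3 each). Genes with at least 1 count numbered 19289, 19518 and 19038 in EKO_exo replicates 1, 2 and 3, fewer than in any of the 6 other libraries (19989 to 20568). On the first principal component, holding 18.8% of the variance of log2 CPM, EKO_exo replicate 3 lay at 61.6 and the other 8 libraries between -16.0 and -3.8. On the second, holding 15.7%, EKO_exo replicate 1 lay at -54.0 and the other 8 between -7.1 and 14.2. On the third, holding 13.4%, EKO_exo replicate 2 lay at -36.4 and the other 8 between -12.9 and 25.3. Coordinates below refer to the mouse genome build GRCm38.

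The first comparison asked which mRNAs of activated CD4+ T cells differed after exposure to exosomes of ApoE-deficient BMDM, relative to PBS. Cell cycle genes fell: of 34 measured members of the list of cell cycle and DNA replication genes, 26 were lower, 1 was higher and 7 did not pass the test. Mki67, which encodes the proliferation marker Ki-67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), went from 488.9 ± 7.33 CPM in PBS to 346.7 ± 8.46 CPM in EKO_exo (SD, n = 3 each), a log2 fold change of -0.50 ± 0.035 (SE). Top2a, a DNA topoisomerase of dividing cells (ENSMUSG00000020914, chromosome 11, 98992943 to 99024189), fell by 0.61 ± 0.047 on the log2 scale, and Rrm2, a subunit of ribonucleotide reductase, fell by 0.55 ± 0.051. Of 22 glycolysis genes 12 fell, and 6 of 13 for fatty acid synthesis. Of 23 NF-kB targets 7 rose, as did 15 of 28 genes of the interferon gamma response and antigen presentation; of 21 genes of naive, resting T cells 10 rose and 1 fell. Among these lists, cell cycle included, only NF-kB targets kept a call with an estimated correlation.

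Among the cell cycle genes the median log2 fold change was -0.33, with 1 higher and 31 lower when adjusted over the list alone (limma camera, adjusted p = 3.38e-23). The list's call was lost in a test that estimated how far its genes vary together (adjusted p = 0.164 with an estimated correlation). Mki67 had an adjusted p of 6.06e-10, Top2a of 1.46e-09 and Rrm2 of 7.69e-08 (edgeR quasi-likelihood, Benjamini-Hochberg). The member that rose was Ccnd2, encoding cyclin D2, at 0.12 ± 0.028 log2, a gene picked out after its value was seen. EKO_exo replicates 1 and 3 were those apart on the first and second principal components, and the list's median without them is given below.

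Among the glycolysis genes 12 fell and 0 rose, with 15 lower and 1 higher when adjusted over the list alone. Their median log2 fold change was -0.16 (camera adjusted p = 2.58e-08; adjusted p = 0.195 with an estimated correlation). Slc16a3, which encodes a lactate transporter (ENSMUSG00000025161, chromosome 11, 120948480 to 120960868), went from 76.3 ± 4.96 to 43.9 ± 3.79 CPM, or -0.80 ± 0.072 log2. Tpi1, triosephosphate isomerase, was at -0.39 ± 0.040 and Pkm, pyruvate kinase, at -0.23 ± 0.028; adjusted p was 4.49e-08, 3.79e-07 and 4.21e-06 for Slc16a3, Tpi1 and Pkm (edgeR quasi-likelihood). Of 18 hypoxia response genes, 2 fell and 5 were lower when adjusted over the list alone. The median was -0.17 (camera adjusted p = 0.000531; adjusted p = 0.203 with an estimated correlation). Those 2 were Egln3, an oxygen-sensing prolyl hydroxylase, at -0.42 ± 0.068, and Ak4, an adenylate kinase, at -0.63 ± 0.108.

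Among 13 fatty acid synthesis genes, 6 fell and 9 were lower when adjusted over the list alone, with a median of -0.26 (camera adjusted p = 2.63e-05; adjusted p = 0.138 with an estimated correlation). Scd2, a stearoyl-CoA desaturase, fell from 501 ± 24.7 to 344 ± 24.5 CPM. Fads2, a desaturase of polyunsaturated fatty acids (ENSMUSG00000024665, chromosome 19, 10062765 to 10101746), was at -1.08 ± 0.221 log2, the largest fall among the named genes with a fold estimate. Srebf1, a transcription factor that controls lipid synthesis genes, was at -0.24 ± 0.046. Of 25 genes of cholesterol synthesis and uptake 4 fell, and 4 when adjusted over the list alone. The median was -0.08 (camera adjusted p = 0.00198; adjusted p = 0.406 with an estimated correlation, and 0.0611 without EKO_exo replicate 1). Stard4, a carrier of cholesterol, was at -0.27 ± 0.067 and Lss, lanosterol synthase, at -0.30 ± 0.077. Stard4 lost its call without EKO_exo replicate 2 or PBS replicate 1 or 2 (edgeR adjusted p up to 0.127) and Lss without EKO_exo replicate 1 or 2 or PBS replicate 2 (up to 0.194). Cyp51 also fell.

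Among 23 NF-kB targets 7 rose and 0 fell, with 13 higher when adjusted over the list alone. Their median was 0.15 (camera adjusted p = 1.79e-07), and this list kept its call with an estimated correlation (adjusted p = 0.0417 with an estimated correlation). Nfkbiz, an atypical inhibitor of the NF-kB family (ENSMUSG00000035356, chromosome 16, 55811375 to 55838899), went from 71.0 ± 2.55 to 88.2 ± 1.42 CPM. Nfkbid rose by 0.17 ± 0.039 log2, and the NF-kB subunit gene Rel by 0.18 ± 0.041, a call lost without PBS replicate 1 (edgeR adjusted p = 0.0554). Of 28 genes of the interferon gamma response and antigen presentation 15 rose and 0 fell, with 19 higher when adjusted over the list alone. The median was 0.13 (camera adjusted p = 1.73e-07; adjusted p = 0.196 with an estimated correlation). B2m, the light chain of MHC class I molecules, rose by 0.19 ± 0.024, the guanylate-binding protein gene Gbp4 by 0.30 ± 0.045 and the immunity-related GTPase gene Igtp by 0.19 ± 0.030.

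Among 23 activation and costimulation genes 8 rose and 2 fell, with 15 higher and 2 lower when adjusted over the list alone. The median was 0.11 (camera adjusted p = 3.56e-05; adjusted p = 0.253 with an estimated correlation). Nr4a3, an immediate early gene of T cell receptor signalling, rose by 0.31 ± 0.035 and the transcription factor gene Irf8 by 0.27 ± 0.030. The members that fell were Tfrc, the receptor through which growing cells take up transferrin-bound iron, at -0.27 ± 0.033, and Il2ra, a subunit of the IL-2 receptor, at -0.10 ± 0.026. Of 21 genes of naive and quiescent T cells 10 rose and 1 fell, with 12 higher and 1 lower when adjusted over the list alone. The median was 0.14 (camera adjusted p = 1.79e-07; adjusted p = 0.138 with an estimated correlation). Ccr7, a homing receptor for lymph nodes, went from 742 ± 14.8 to 904 ± 16.9 CPM and Klf2, a transcription factor of quiescence, from 63.6 ± 2.14 to 88.6 ± 4.76 CPM, while Satb1, a chromatin organizer, fell by 0.19 ± 0.028 log2.

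Camera also called 6 further lists. In the unfolded protein response 5 of 19 genes fell, 9 when adjusted over the list alone, with Hsp90b1 at -0.22 ± 0.031 and Pdia6 at -0.21 ± 0.037. The median was -0.07 (camera adjusted p = 0.000823; adjusted p = 0.195 with an estimated correlation). In T cell receptor and CD28 signalling 6 of 25 rose, with 8 higher and 1 lower when adjusted over the list alone, among them the kinase gene Fyn at 0.19 ± 0.035 and the receptor chain gene Cd247 at 0.15 ± 0.034. The median was 0.04 (camera adjusted p = 0.00314; adjusted p = 0.164 with an estimated correlation). Of 58 ribosomal protein genes 6 rose, 7 when adjusted over the list alone, with Rps20 at 0.26 ± 0.040 and Rps16 at 0.25 ± 0.042. The median was 0.05 (camera adjusted p = 0.00641). That call was lost without EKO_exo replicate 2 (0.0814) or PBS replicate 3 (0.087), and had an adjusted p = 0.523 with an estimated correlation. Of 12 targets of miR-146a in innate signalling 3 rose, and 3 when adjusted over the list alone, Notch1 and Traf6 among them. The median was 0.13 (camera adjusted p = 0.0132; adjusted p = 0.266 with an estimated correlation, and 0.0621 without EKO_exo replicate 2). Notch1 lost its call without EKO_exo replicate 1 or PBS replicate 1 or 2 (edgeR adjusted p up to 0.124) and Traf6 without EKO_exo replicate 2 or 3 or any one PBS library (up to 0.125). The apoptosis and p53 list had 5 of 20 genes higher, 6 when adjusted over the list alone, with Gadd45b at 0.31 ± 0.060. The median was 0.04 (camera adjusted p = 0.0419; adjusted p = 0.417 with an estimated correlation). In the list of Th1 genes, those of the interferon gamma-producing helper class, 3 of 21 rose, with 7 higher and 2 lower when adjusted over the list alone, among them Hopx at 0.45 ± 0.108, a call lost without EKO_exo replicate 3 or PBS replicate 2 or 3 with an edgeR adjusted p of up to 0.103. The median was 0.09 (camera adjusted p = 0.0463; adjusted p = 0.203 with an estimated correlation). Leaving out single libraries took the camera adjusted p as high as 0.236 for the apoptosis list, which lost its call without EKO_exo replicate 1 or 2 or PBS replicate 1 or 3. The Th1 call was lost without EKO_exo replicate 2 or 3, PBS replicate 2 or 3 or WT_exo replicate 3, with an adjusted p of up to 0.146. On all libraries the apoptosis and Th1 calls were lost with the replicate block (camera adjusted p = 0.0602 and 0.0726) and with a filter at a mean of 5 CPM (0.059 and 0.0688).

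The fit without EKO_exo replicates 1 and 3, the libraries apart on the first and second principal components, was chosen after the data were seen. It leaves 1 EKO_exo library, replicate 2, which was itself apart on the third component. PBS and WT_exo alone supply the spread in this fit. Counts fall with fewer libraries whether or not the shifts do. In it the members called lower against PBS went from 12 to 7 for glycolysis, 6 to 2 for fatty acid synthesis, 5 to 2 for the unfolded protein response and 4 to 0 for cholesterol synthesis and uptake. Those called higher went from 15 to 9 for the interferon gamma response, 10 to 4 for naive T cells, 8 to 6 for activation, 7 to 3 for NF-kB targets and 5 to 1 for apoptosis. T cell receptor and CD28 signalling went from 6 to 0, and miR-146a targets, Th1 genes and B cell markers each from 3 to 0. Ribosomal proteins stayed at 6 and the hypoxia response at 2. The lists for cholesterol synthesis (camera adjusted p = 0.0727), Th1 genes (0.124) and apoptosis (0.201) lost their calls. The median log2 fold change was -0.326 for cell cycle, -0.150 for glycolysis, -0.195 for fatty acid synthesis, 0.127 for the interferon gamma response, 0.123 for NF-kB targets and 0.091 for naive T cells. It was 0.064 for T cell receptor and CD28 signalling, 0.098 for miR-146a targets, 0.122 for Th1 genes, -0.082 for cholesterol synthesis, -0.088 for hypoxia and 0.009 for B cell markers.

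Lists without a call still held changed genes. Of 18 IL-2 and STAT5 signalling genes 5 rose and 1 fell, with 5 higher and 2 lower when adjusted over the list alone (median 0.07, camera adjusted p = 0.121); Pim2, a survival kinase, was at 0.21 ± 0.032 and Pim1 at 0.18 ± 0.030. The ribosome biogenesis list had 3 of 27 lower, 1 higher and 3 lower when adjusted over the list alone (median -0.01, camera adjusted p = 0.353), namely Npm1 at -0.21 ± 0.027, Ncl at -0.14 ± 0.024 and Rrp12 at -0.19 ± 0.042, the last lost without PBS replicate 2 (edgeR adjusted p = 0.0789). In the list of serine, one-carbon and amino acid response genes 1 of 22 rose and 3 fell, with 2 higher and 4 lower when adjusted over the list alone (median -0.04, camera adjusted p = 0.288); Asns, asparagine synthetase, was at -0.23 ± 0.048 and the amino acid transporter gene Slc38a2 at 0.17 ± 0.037. The lists for Th2 genes (median -0.26, adjusted p = 0.0846), Th17 genes (0.10, 0.353), regulatory T cells (0.06, 0.145) and inhibitory receptors (0.08, 0.112) were not called by camera, the numbers being the median and the adjusted p. Each had 1 member past the test over all genes: Ccr4 and Il21 fell, and Gpr83 and Cd274 rose. When adjusted over the list alone these 4 had 0, 1, 4 and 4 members higher and 2, 2, 1 and 1 lower, in that order. Also not called were tricarboxylic acid cycle (median -0.05, camera adjusted p = 0.112, 2 of 19 lower, 2 when adjusted over the list alone), fatty acid oxidation (-0.02, 0.710, 1 of 21 lower, 1 alone), cholesterol efflux and LXR targets (-0.14, 0.616, 1 higher and 1 lower of 16, 2 and 2 alone), nuclear oxidative phosphorylation (-0.01, 0.846, 2 of 46 lower, 1 higher and 2 lower alone), mitochondrially encoded mRNAs (-0.05, 0.260, 1 of 7 lower, 2 alone), heat shock and early stress (-0.05, 0.638, 2 of 18 lower, 3 alone) and type I interferon (0.03, 0.779, 1 of 31 higher, 1 alone). The members behind these counts included Suclg1, Hadh, Nr1h2 (higher) and Scarb1 (lower), Ndufv1 and Atp5b, mt-Cytb, Hspd1 and Hsp90aa1, and Parp14, in that order. Histone mRNAs had a median of -0.48 (camera adjusted p = 0.0816) and 0 of 16 past the test in either count.

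Markers of other cells were measured in the same libraries. In the list of B cell markers 3 of 17 rose, 3 when adjusted over the list alone: Igkc by 0.28 ± 0.06, Ighm by 0.16 ± 0.037 and Cd74 by 0.18 ± 0.053. The median was 0.10 (camera adjusted p = 0.103). Each of these calls was lost without PBS replicate 1, and those of Ighm and Cd74 also without PBS replicate 3; Cd74 was lost as well without any one of 6 other libraries, with edgeR adjusted p up to 0.0569, 0.0619 and 0.166. The macrophage and monocyte list had 2 of 23 higher, 2 when adjusted over the list alone, Csf1r and Ctss. The median was 0.10 (camera adjusted p = 0.147). Dendritic cell markers (median 0.09, camera adjusted p = 0.199, 1 of 10 higher, Irf8, 1 alone), neutrophil markers (0.13, 0.754, 0 of 6), CD8 T cell markers (-0.21, 0.806, 1 of 6 higher, Eomes, 1 alone) and NK cell markers (0.16, 0.371, 0 of 7) were not called. Csf1r, Ctss and Eomes were picked out after their values were seen. Erythroid and platelet markers had 2 and 4 members measured, too few for a test as lists. The erythroid members Car1 and Car2, carbonic anhydrase genes, were at -0.81 ± 0.509 and -0.99 ± 0.274 log2; Car2 passed (edgeR adjusted p = 0.0299, 4.24 CPM in PBS and 2.12 in EKO_exo) and was picked out after its value was seen. Platelet markers had a median of -0.02 and 0 of 4 past the test.

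Genes with the largest changes at a mean of at least 5 CPM lay mostly outside these lists. Lad1, which encodes an anchoring filament protein (ENSMUSG00000041782, chromosome 1, 135818598 to 135833342), went from 181 ± 7.88 CPM in PBS to 269 ± 14.6 CPM in EKO_exo, or 0.57 ± 0.043 log2 (edgeR adjusted p = 1.34e-09). Serpine2, a protease inhibitor, rose by 0.76 ± 0.178, Phlda1 by 0.57 ± 0.102, Ccdc141 by 0.52 ± 0.085, and Arhgef4, Mturn, Med29 and L1cam by 0.55 to 0.59. Jag2, a Notch ligand, fell by 0.81 ± 0.141, Ajuba by 0.76 ± 0.116, the transglutaminase gene Tgm2 by 0.76 ± 0.133 and the mitotic kinase gene Mastl by 0.73 ± 0.140; H2-DMb2 fell by 0.94 ± 0.255 and Cenpw by 0.79 ± 0.196. Single left-out libraries ended the calls of Arhgef4 (EKO_exo 3 or any PBS library, edgeR adjusted p up to 0.174), Mturn (EKO_exo 1, PBS 1 or 2, up to 0.158), Med29 (EKO_exo 2, PBS 1 or 2, up to 0.0737), L1cam (EKO_exo 1, 0.0595), H2-DMb2 (EKO_exo 3, PBS 1 or 3, up to 0.128) and Cenpw (EKO_exo 3, PBS 1 or 2, up to 0.107). The gene for apolipoprotein E itself, Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), stood at 15.04 ± 1.62 CPM in PBS and 17.8 ± 1.13 CPM in EKO_exo (0.24 ± 0.114 log2, edgeR adjusted p = 0.270). Neither Il2 (-0.01 ± 0.107), Ifng (0.37 ± 0.199), Foxp3 (0.12 ± 0.043), Cd4 (0.03 ± 0.027) nor Irak1 (-0.02 ± 0.046) passed the test. Traf6 was at 0.14 ± 0.039 (edgeR adjusted p = 0.0296).

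In all, 746 of 14684 genes changed (325 higher, 421 lower; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under the threshold of 0.05), with a median fold of 1.19; 60 changed by more than 1.5-fold and 19 by more than 2-fold. The groups did not overlap for 723 of the 746, and for 20.5% of all genes tested, where 10% are given by chance. Camera called 15 of 36 lists, and 1 with an estimated correlation. The count of genes was 399 without PBS replicate 1 and 375 without PBS replicate 2. In a fit to only the EKO_exo and PBS libraries it was 602. Leaving out PBS replicate 3 or EKO_exo replicate 1 ended the call of Serpine2, and EKO_exo replicate 1 or PBS replicate 1 or 2 that of Il2ra, with adjusted p up to 0.125 and 0.135.

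**Figure D1:**
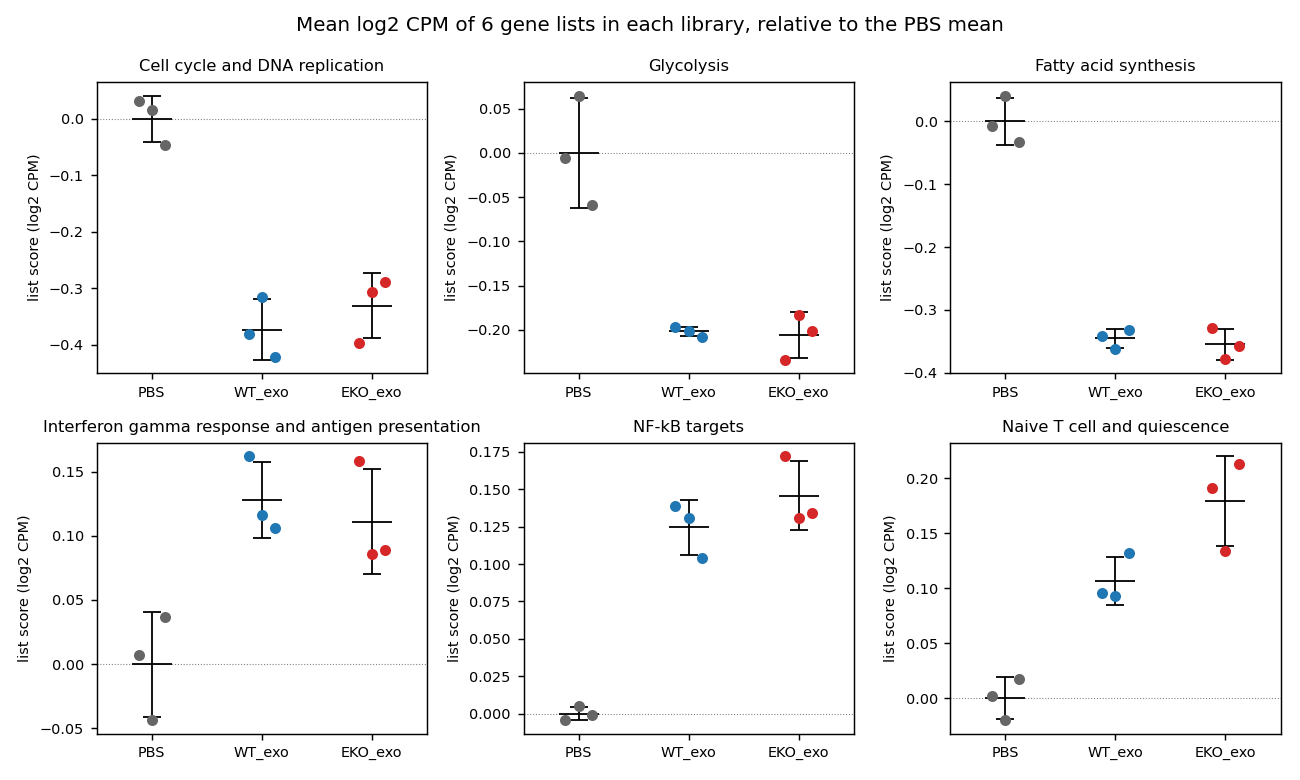
Mean log2 CPM of the members of 6 gene lists in each library, relative to the mean of the 3 PBS libraries. Points are libraries, long bars are group means and error bars are 1 SD (n = 3); the cell cycle score averaged -0.37 in WT_exo and -0.33 in EKO_exo, and the NF-kB score 0.13 and 0.15.

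The second comparison asked the same of exosomes from wild-type BMDM, relative to PBS. Cell cycle genes were lower here too: 29 of 34 fell, 1 rose (Ccnd2, by 0.13 ± 0.028 log2) and 4 did not pass. Mki67 went from 488.9 ± 7.33 to 329.4 ± 12.7 CPM (SD, n = 3 each), or -0.57 ± 0.035 log2; Top2a was at -0.60 ± 0.047 and Rrm2 at -0.53 ± 0.051. Of 22 glycolysis genes 12 fell and 1 rose, and 6 of 13 fatty acid synthesis genes fell, with Slc16a3 at -0.70 ± 0.071 and Fads2 at -1.45 ± 0.223. Higher were 8 of 23 NF-kB targets, 13 of 28 interferon gamma response genes and 5 of 21 naive T cell genes, of which 1 was lower, with Nfkb2 at 0.21 ± 0.035, Tap2 at 0.25 ± 0.036 and Ccr7 at 0.31 ± 0.028. Again only the NF-kB list among these kept its call with an estimated correlation.

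Adjusted over the list alone, 31 cell cycle genes were lower and 1 higher; the median was -0.39 (camera adjusted p = 7.95e-29; adjusted p = 0.138 with an estimated correlation). For glycolysis 12 of 22 fell and 1 rose, with 16 lower and 1 higher when adjusted over the list alone. The median was -0.17 (camera adjusted p = 2.44e-09; adjusted p = 0.195 with an estimated correlation). Tpi1 was at -0.40 ± 0.040 and Pkm at -0.26 ± 0.028, and the member that rose, Eno3, encodes the muscle form of enolase and was picked out after its value was seen. In fatty acid synthesis 6 of 13 fell, and 6 when adjusted over the list alone, including Scd2 (501 ± 24.7 to 332 ± 3.92 CPM) and the elongase gene Elovl6 at -0.49 ± 0.079. The median was -0.17 (camera adjusted p = 7.72e-05; adjusted p = 0.138 with an estimated correlation). In cholesterol synthesis and uptake 3 of 25 fell, and 3 when adjusted over the list alone, among them Cyp51 and Lss, whose calls were lost without PBS replicate 1 or WT_exo replicate 1 (Cyp51, edgeR adjusted p up to 0.0717) and PBS replicate 2 or 3 or any WT_exo library (Lss, up to 0.316). The median was -0.11 (camera adjusted p = 0.00641; adjusted p = 0.411 with an estimated correlation). The hypoxia response had 4 of 18 lower, 5 when adjusted over the list alone, with Ak4 at -0.58 ± 0.108 and Egln3 at -0.35 ± 0.068. The median was -0.15 (camera adjusted p = 0.000103; adjusted p = 0.195 with an estimated correlation). The unfolded protein response had 6 of 19 lower, 9 when adjusted over the list alone, with Pdia6 at -0.24 ± 0.037 and Calr at -0.14 ± 0.027. The median was -0.10 (camera adjusted p = 0.000166; adjusted p = 0.164 with an estimated correlation).

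Among NF-kB targets 8 of 23 rose, 14 when adjusted over the list alone (median 0.13, camera adjusted p = 1.18e-07), and the call held at an adjusted p = 0.0417 with an estimated correlation. In the list of interferon gamma response and antigen presentation genes 13 of 28 rose, 17 when adjusted over the list alone. The median was 0.12 (camera adjusted p = 1.18e-07; adjusted p = 0.195 with an estimated correlation). Beside Tap2, a peptide transporter, Irf1 was at 0.22 ± 0.032 and Igtp at 0.20 ± 0.030. Activation and costimulation genes had 8 of 23 higher and 2 lower, and 12 higher and 2 lower when adjusted over the list alone. The median was 0.12 (camera adjusted p = 5.86e-05; adjusted p = 0.265 with an estimated correlation). Irf8 was at 0.31 ± 0.030 and Nr4a3 at 0.29 ± 0.035, while Tfrc was at -0.25 ± 0.033 and Il2ra at -0.12 ± 0.026. For naive and quiescent T cells 5 of 21 rose and 1 fell, with 7 higher and 1 lower when adjusted over the list alone, among them Actn1 at 0.24 ± 0.032 and Btg1 at 0.25 ± 0.039. The median was 0.07 (camera adjusted p = 0.000485; adjusted p = 0.195 with an estimated correlation). Of the 12 miR-146a targets 3 rose, again with Notch1 and Traf6, and 5 when adjusted over the list alone. The median was 0.14 (camera adjusted p = 0.00314; adjusted p = 0.203 with an estimated correlation). Notch1 lost its call without PBS replicate 1 (edgeR adjusted p = 0.0682), and Traf6 without any PBS or WT_exo library or EKO_exo replicate 2 (up to 0.193).

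For Th2 genes, those of the helper class that makes IL-4, 2 of 15 fell, with 1 higher and 3 lower when adjusted over the list alone. The median was -0.29 (camera adjusted p = 0.00198; adjusted p = 0.195 with an estimated correlation). The chemokine receptor gene Ccr4 went from 102 ± 4.10 to 72.2 ± 1.82 CPM and Il4ra was at -0.16 ± 0.032. Mitochondrially encoded mRNAs had 3 of 7 lower, 3 when adjusted over the list alone, namely mt-Cytb at -0.20 ± 0.026, mt-Nd4 at -0.20 ± 0.035 and mt-Nd5 at -0.16 ± 0.033. The median was -0.16 (camera adjusted p = 0.0120; adjusted p = 0.406 with an estimated correlation). Inhibitory receptors had 3 of 15 higher, 4 when adjusted over the list alone, including Cd274, the ligand of PD-1, at 0.23 ± 0.056. The median was 0.14 (camera adjusted p = 0.0260; adjusted p = 0.195 with an estimated correlation). The list's call was lost without PBS replicate 1 or WT_exo replicate 1 or 3 (camera adjusted p up to 0.118), and that of Cd274 without PBS replicate 1 or 2 or WT_exo replicate 1 (edgeR adjusted p up to 0.111). The Th1 list had 4 of 21 higher, 7 when adjusted over the list alone, with Tbx21, the transcription factor of that class, at 0.19 ± 0.039. The median was 0.11 (camera adjusted p = 0.0472; adjusted p = 0.203 with an estimated correlation). For nuclear oxidative phosphorylation genes 0 of 46 passed either count. The median was -0.04 (camera adjusted p = 0.0419; adjusted p = 0.627 with an estimated correlation). The Th1 call was lost without any one of the EKO_exo replicates, PBS replicate 2 or 3 or WT_exo replicate 2 (up to 0.132), and the oxidative phosphorylation call without EKO_exo, PBS or WT_exo replicate 1 or 2 (up to 0.343). Both were lost without EKO_exo replicates 1 and 3 together (camera adjusted p = 0.0928 and 0.0727) and, on all libraries, with the replicate block (0.0832 and 0.0545). The Th1 call was also lost with a filter at a mean of 5 CPM (0.0566).

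Lists not called included T cell receptor and CD28 signalling (median 0.02, camera adjusted p = 0.257), with 3 of 25 higher and 4 when adjusted over the list alone. IL-2 and STAT5 signalling (0.08, 0.170) had 3 higher and 2 lower of 18, with 7 and 3 when adjusted over the list alone. Apoptosis and p53 targets (0.01, 0.400) had 2 higher and 1 lower of 20, with 4 and 2 alone, ribosomal proteins (0.03, 0.053) 3 of 58 higher, 5 alone, and ribosome biogenesis (-0.01, 0.702) 3 of 27 lower, 3 alone. The serine, one-carbon and amino acid response list (-0.02, 0.690) had 2 higher and 1 lower of 22, with 2 and 2 alone. Th17 genes (0.17, 0.257), regulatory T cell genes (0.06, 0.145), the tricarboxylic acid cycle (-0.04, 0.0908), fatty acid oxidation (-0.02, 0.609), cholesterol efflux and LXR targets (-0.14, 0.555), heat shock (-0.06, 0.201), type I interferon (-0.10, 0.186) and histone mRNAs (-0.32, 0.147) had 0 to 2 members past the test over all genes, among them Il21, Capg (higher), Suclg1, Hadh, Nr1h2 (higher), and Hspa8 and Hspd1. When adjusted over the list alone these 8 lists had 1, 4, 0, 0, 1, 0, 0 and 0 members higher and 2, 0, 3, 1, 1, 3, 0 and 0 lower, in that order. Markers of B cells (-0.02, 0.661; 1 of 17 higher, Cd74, 1 alone), macrophages and monocytes (0.13, 0.224; 0 of 23), dendritic cells (0.03, 0.275; 1 of 10 higher, Irf8, 2 alone), neutrophils (0.19, 0.923; 1 of 6 lower, S100a9, 1 alone), CD8 T cells (-0.22, 0.353; 0 of 6, 1 higher and 1 lower alone) and NK cells (0.01, 0.923; 1 of 7 lower, Gzma, 1 alone) were not called. S100a9 and Gzma were picked out after their values were seen. Among erythroid markers Car1 was at -1.27 ± 0.516 and Car2 at -0.40 ± 0.266, with 0 of 2 past the test and 1 lower when adjusted over the list alone; platelet markers had a median of 0.24 and 0 of 4.

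Of the genes with the largest changes, Lad1 (181 ± 7.88 to 268 ± 5.51 CPM), Serpine2 (7.11 ± 0.783 to 13.8 ± 2.38 CPM) and Ccdc141 (0.56 ± 0.084 log2) rose, as did Hyls1 and Tbc1d30, by 0.49 ± 0.099 and 0.47 ± 0.076, and Ccl3, Lzts2 and Ttll3, by 0.48 to 0.71. Jag2 was at -1.249 ± 0.143, Tgm2 at -0.96 ± 0.133, Dscc1, a cohesion factor at replication forks, at -0.84 ± 0.133, the ubiquitin ligase gene Nedd4 at -0.83 ± 0.1, and Mrnip and Stra6 at -0.91 ± 0.222 and -0.89 ± 0.218. Ighg2c, the constant region of an antibody heavy chain, was at -1.14 ± 0.211 (edgeR adjusted p = 0.0009). Apoe averaged 18.1 CPM against 15.04 CPM in PBS (0.26 ± 0.113 log2, edgeR adjusted p = 0.232). Il2 (0.01 ± 0.107), Ifng (0.49 ± 0.198), Foxp3 (0.01 ± 0.043), Cd4 (-0.07 ± 0.027) and Irak1 (0.00 ± 0.045) did not pass, and Traf6 was at 0.13 ± 0.039 (edgeR adjusted p = 0.046).

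In all, 730 of 14684 genes changed (269 higher, 461 lower; edgeR quasi-likelihood, Benjamini-Hochberg), with a median fold of 1.20; 79 changed by more than 1.5-fold and 22 by more than 2-fold. The groups did not overlap for 722 of the 730, and for 22.2% of all genes tested, where 10% are given by chance. Camera called 16 of 36 lists, and 1 with an estimated correlation. The count of genes was 410 without PBS replicate 1, 399 without PBS replicate 2, and 441, 430 and 432 without WT_exo replicates 1, 2 and 3. In a fit to only the WT_exo and PBS libraries it was 1068, where the same kind of fit gave 602 for EKO_exo against PBS. The similar totals of 730 and 746 therefore depend on the spread shared by the 3 groups. Single left-out libraries ended the calls of Ccl3 (any PBS or WT_exo library or EKO_exo 2, edgeR adjusted p up to 0.352), Lzts2 (PBS 1 or 2, WT_exo 2 or 3, up to 0.251), Ttll3 (PBS 1 or 2, any WT_exo library, up to 0.168), Mrnip (PBS 2, WT_exo 1, up to 0.117) and Stra6 (PBS 2, WT_exo 2 or 3, up to 0.134).

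**Figure D2:**
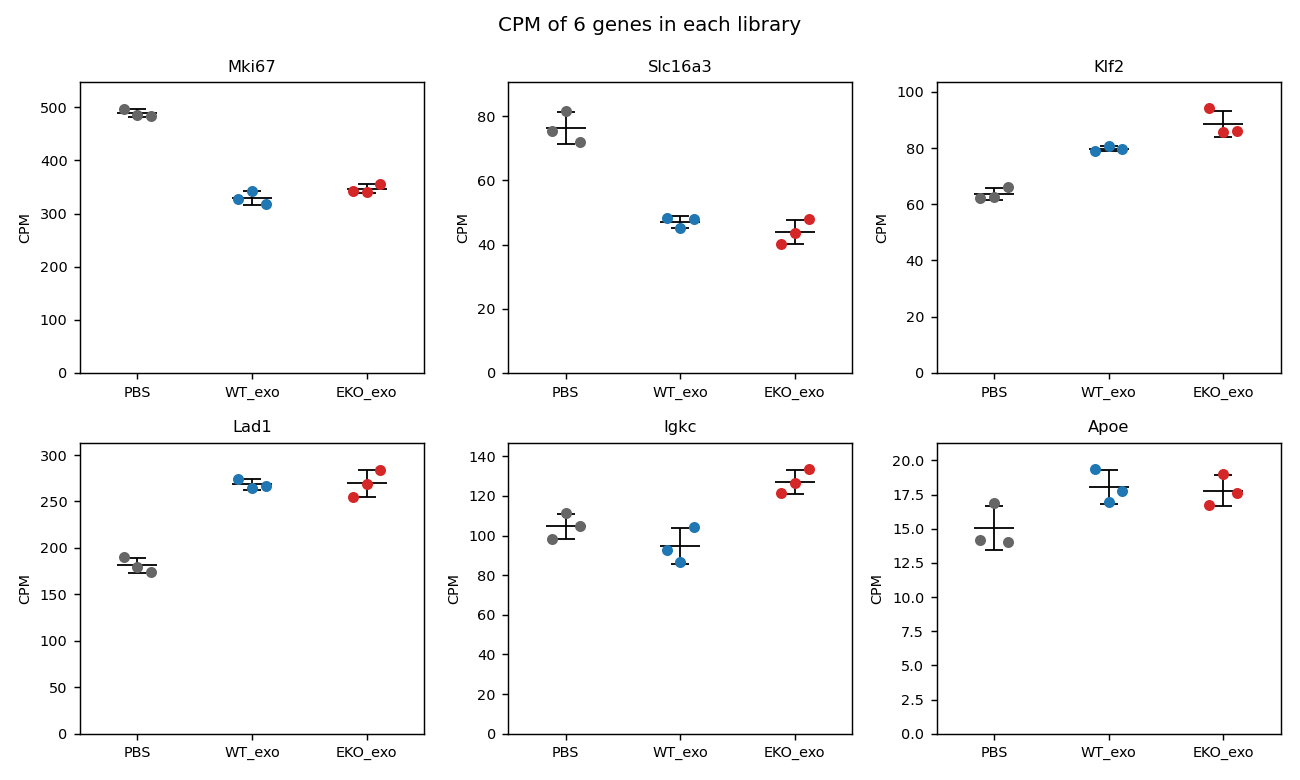
CPM of 6 genes in each library of the 3 groups. Points are libraries, long bars are means and error bars are 1 SD (n = 3); Mki67 lay at 488.9 in PBS, 329.4 in WT_exo and 346.7 in EKO_exo on average, and Apoe at 15.04, 18.1 and 17.8.

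Fold changes of the exosome groups against PBS moved together. Across 14684 genes their Pearson r was 0.516, where simulated groups without any effect, sharing PBS libraries, gave 0.498 on average (SD 0.0134, highest of 100 simulations 0.529). Their covariance was 0.0941 against 0.0695 simulated, a difference of 0.0246. Among the 9568 genes at a mean of at least 5 CPM the r was 0.736 against 0.501, and the covariance 0.0178 against 0.00514, a difference of 0.0127. These are correlations across genes, which are not independent replicates. Genes higher in both numbered 161, where independent lists of these sizes would share 5.95 and the simulations 0.01. Genes lower in both numbered 293, against 13.2 and 0, and 0 were called in opposite directions. The simulations held no effect, so almost no gene could be called in both, and shared PBS libraries break the independence. Neither is therefore a baseline for the number of shared calls. Mki67, Slc16a3, Fads2 and Jag2 were among the 293 and Lad1 and Ccr7 among the 161. Each comparison used the same 3 PBS libraries, too few to split, so part of the overlap, and of the excess in r and covariance, may come from them. The 454 shared calls became 262 without PBS replicate 1 and 244 without PBS replicate 2.

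**Figure D3:**
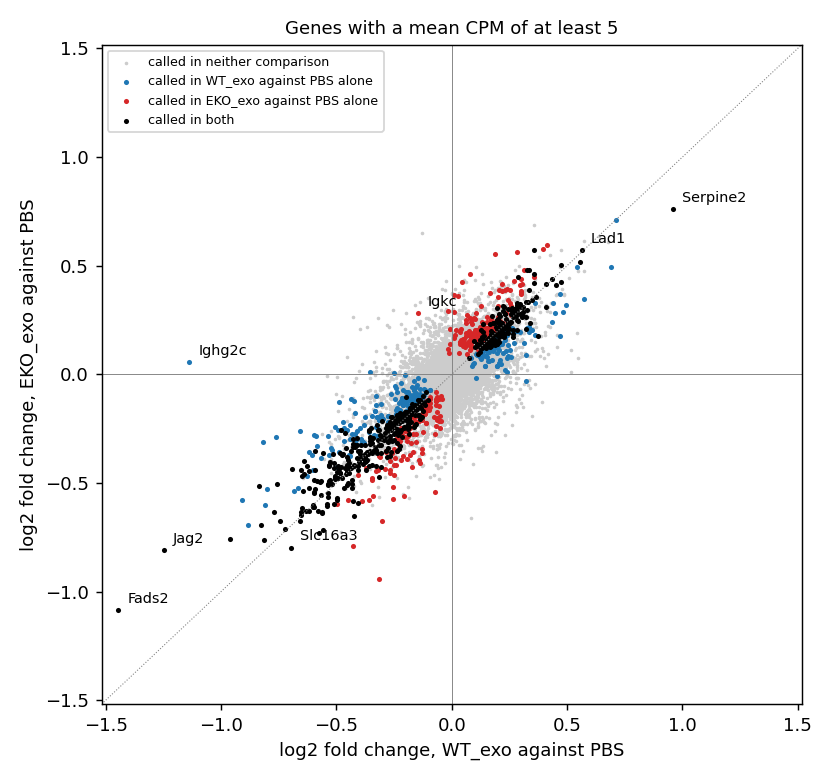
Log2 fold change against PBS of each of 9568 genes at a mean of at least 5 CPM, in WT_exo (horizontal) and EKO_exo (vertical); the dotted diagonal marks equal changes. Black points (449) passed the test in both comparisons, red (271) in EKO_exo alone and blue (256) in WT_exo alone, and Igkc and Ighg2c lie off the diagonal.

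The third comparison set exosomes of ApoE-deficient against those of wild-type BMDM and so asked what differed with the donor's ApoE. The labels used here do not give the number of exosome preparations or donors behind each group. A difference with donor genotype could therefore not be told apart from a difference between preparations. Only 5 genes passed: Igkc, Ighg2c, mt-Nd4 and B2m were higher in EKO_exo and Tpt1 was lower. Igkc, the constant region of the antibody kappa light chain (ENSMUSG00000076609, chromosome 6, 70726435 to 70726966), was at 127 ± 6.08 CPM in EKO_exo, 94.6 ± 9.04 in WT_exo and 105 ± 6.43 in PBS (SD, n = 3 each), a log2 difference of 0.43 ± 0.061 (edgeR adjusted p = 0.00219). Ighg2c (ENSMUSG00000076612, chromosome 12, 113285325 to 113288932) was at 9.34 ± 0.922, 4.09 ± 1.00 and 8.97 ± 2.83 CPM in the same order. Mki67, Il2ra and Klf2, all of which changed against PBS, did not pass here, at 0.07 ± 0.035, 0.02 ± 0.026 and 0.15 ± 0.057 log2.

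The mitochondrially encoded mt-Nd4, a subunit of respiratory complex I (ENSMUSG00000064363, mitochondrial, 10167 to 11544), was at 791 ± 23.6 CPM in EKO_exo and 690 ± 30.9 in WT_exo, or 0.20 ± 0.035 log2. B2m (ENSMUSG00000060802, chromosome 2, 122147686 to 122153083) was at 2247 ± 52.8 and 2055 ± 44.6 CPM, or 0.13 ± 0.024 log2. Tpt1, which encodes translationally controlled tumor protein (ENSMUSG00000060126, chromosome 14, 75845093 to 75848525), was at 1126 ± 15.3 and 1262 ± 57.5 CPM, or -0.17 ± 0.029 log2. Adjusted p was 0.0207 for mt-Nd4, Ighg2c and Tpt1 and 0.0403 for B2m (edgeR quasi-likelihood, Benjamini-Hochberg). All 3 EKO_exo libraries lay on one side of all 3 WT_exo libraries for each of the 5 genes, as for 11.8% of all genes, where 10% are given by chance.

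Camera called 5 lists, each with 0 members past the test over all genes. They were the type I interferon response (31 genes, median 0.08, camera adjusted p = 0.0270; adjusted p = 0.572 with an estimated correlation), nuclear oxidative phosphorylation (46 genes, 0.04, 0.0319; adjusted p = 0.603 with an estimated correlation), naive T cells (21 genes, 0.02, 0.0380; adjusted p = 0.406 with an estimated correlation), cell cycle (34 genes, 0.03, 0.0419; adjusted p = 0.657 with an estimated correlation) and T cell receptor and CD28 signalling (25 genes, 0.03, 0.0419; adjusted p = 0.203 with an estimated correlation). When adjusted over the list alone, 3 naive T cell genes and 4 of T cell receptor signalling were higher, and 0 in the other 3 lists. Values for members that did not pass included Irf7 at 0.44 ± 0.129, Isg15 at 0.53 ± 0.200, S1pr1 at 0.28 ± 0.069, Birc5 at 0.24 ± 0.091, Ccna2 at 0.18 ± 0.067, Ndufa2 at 0.25 ± 0.092, Cd3e at 0.13 ± 0.034 and Trbc2 at 0.16 ± 0.042. Each call was lost without some single libraries, and all 5 when p was adjusted within this comparison alone (camera adjusted p = 0.095). The highest camera adjusted p was 0.664 for type I interferon (lost without EKO_exo 1 or WT_exo 3), 0.422 for oxidative phosphorylation (EKO_exo 2, WT_exo 1 or 2), 0.158 for naive T cells (EKO_exo 1 or 3, PBS 1, WT_exo 1 or 3), 0.601 for cell cycle (EKO_exo 2 or 3, PBS 1, WT_exo 1 or 3) and 0.164 for T cell receptor signalling (any library but EKO_exo 3 and WT_exo 3). Without EKO_exo replicates 1 and 3 together the calls of naive T cells (camera adjusted p = 0.862), type I interferon (0.938) and T cell receptor signalling (0.118) were lost. On all libraries the replicate block ended the calls of cell cycle (camera adjusted p = 0.0663), naive T cells (0.0644), oxidative phosphorylation (0.0527) and T cell receptor signalling (0.0726), and a filter at a mean of 5 CPM that of oxidative phosphorylation (0.0553).

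Of the lists called against PBS in one exosome group alone, T cell receptor and CD28 signalling and oxidative phosphorylation are given above, with calls that were lost with an estimated correlation (adjusted p = 0.203 and 0.603). The others were not shown to differ between these groups. The medians between EKO_exo and WT_exo were 0.04 for Th2 genes (camera adjusted p = 0.192; 3 higher when adjusted over the list alone), 0.02 for mitochondrially encoded mRNAs (0.103; 1 of 7 higher, mt-Nd4, 3 alone), 0.03 for apoptosis and p53 targets (0.121; 0 of 20, 1 higher alone), 0.01 for ribosomal proteins (0.371; 0 of 58, 3 higher alone) and -0.03 for inhibitory receptors (0.555; 0 of 15 in either count). With the median and the camera adjusted p in parentheses, 0 members passed in either count for glycolysis (0.01, 0.923), fatty acid synthesis (-0.01, 0.899), NF-kB targets (-0.02, 0.923), activation genes (0.01, 0.891), the unfolded protein response (-0.01, 0.811), hypoxia (0.04, 0.779) and miR-146a targets (-0.02, 0.637). The same held for Th1 genes (-0.03, 0.913), Th17 genes (-0.12, 0.744), regulatory T cell genes (0.02, 0.967), the tricarboxylic acid cycle (-0.01, 0.923), fatty acid oxidation (0.01, 0.913), cholesterol efflux and LXR targets (0.00, 0.870), serine and one-carbon genes (-0.03, 0.353), heat shock (0.01, 0.396), ribosome biogenesis (-0.01, 0.439) and histone mRNAs (-0.15, 0.653). Cholesterol synthesis and uptake (-0.03, 0.555) had 1 lower and IL-2 and STAT5 signalling (0.00, 0.870) 1 higher, each when adjusted over the list alone. The interferon gamma list (-0.01, 0.923) had B2m alone higher in both counts.

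B cell markers had a median of 0.11 (camera adjusted p = 0.199), with 1 of 17, Igkc, higher in both counts. The macrophage and monocyte list (-0.02, 0.754) had 2 of 23 higher when adjusted over the list alone, and the lists of dendritic cells (-0.01, 0.923), neutrophils (0.08, 0.555), CD8 T cells (0.14, 0.288) and NK cells (0.02, 0.224) had 0. Apoe differed by -0.02 ± 0.112 log2, Il2 by -0.02 ± 0.107, Ifng by -0.12 ± 0.196, Foxp3 by 0.11 ± 0.043, Cd4 by 0.10 ± 0.027, Irak1 by -0.02 ± 0.046 and Traf6 by 0.01 ± 0.039, and none of these passed.

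The count of 5 of 14684 genes stands beside 1039 at an unadjusted p under 0.05, and the median 95% interval of a gene at 5 CPM or more reached 0.155 log2 to either side. The call of Igkc was lost without WT_exo replicate 1 or 2, with an adjusted p of up to 0.06; the other 4 genes lost theirs without any one of the WT_exo libraries or EKO_exo replicate 2, and with the replicate block. Ighg2c, mt-Nd4 and Tpt1 also lost theirs without EKO_exo replicate 3 (edgeR adjusted p up to 0.352), and B2m without EKO_exo replicate 1 or PBS replicate 2 (up to 0.407). Ighg2c was not called by limma-voom or the Wald test of DESeq2. The count was 1 without EKO_exo replicate 2, WT_exo replicate 1 or WT_exo replicate 3 and 0 without WT_exo replicate 2, and the Wald test of DESeq2 on all libraries called 38.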

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

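The tests of T cell content, of residual B cells and of splits for gene lists were chosen only after the result was seen. In 5 genes the test of EKO_exo against WT_exo passed, though each of these calls was lost without some single libraries. Igkc differed by 0.43 log2 (edgeR adjusted p = 0.00219), being at 0.28 in EKO_exo and -0.14 in WT_exo against PBS. Ighg2c differed by 1.19 (adjusted p = 0.0207), at 0.06 and -1.14. The edgeR difference of mt-Nd4 was 0.20 (adjusted p = 0.0207), at 0.00 and -0.20, and that of B2m 0.13 (adjusted p = 0.0403), at 0.19 and 0.06. For Tpt1 it was -0.17 (edgeR adjusted p = 0.0207), at 0.05 and 0.21.

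Genes of the cell cycle fell in both exosome groups. After every library was thinned to the smallest total, 26 of 34 were called lower in EKO_exo and 29 in WT_exo, as without thinning. Counts were already scaled to library size and the totals differed little, so thinning could hardly have changed these calls. It therefore cannot decide whether library size plays a part. A trend of log2 fold change on GC content and transcript length was also removed, over genes at a mean of at least 5 CPM. For the 33 members among these with both values, the median residual was -0.319 in EKO_exo and -0.41 in WT_exo. This argues against that bias as the whole of the fall. Fewer T cells among the cells would lower genes of T cell receptor and CD28 signalling alike, but their median was 0.038 in EKO_exo and 0.015 in WT_exo. Exposure to exosomes of BMDM stays among the open explanations, untested against vesicles of another source, which were not measured here.

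Of 126 immunoglobulin genes 87 had a log2 fold change above 0 in EKO_exo against WT_exo, with a median of 0.32. Only Igkc and Ighg2c were called, and 105 of the 126 lay under 2 CPM. More residual B cells may account for this and cannot be told apart from other sources. The upper 95% limit for 13 other B cell genes was 0.426, the rise of Igkc itself, and 9 of them lay under 2 CPM. The limits in this paragraph used a spread pooled over the B cell, plasma cell and immunoglobulin lists, not that of each list alone. The 4 better measured B cell genes were lower than Igkc: Cd74 at 0.004 ± 0.053 (SE), H2-Aa at -0.034 ± 0.133, H2-Eb1 at -0.056 ± 0.116 and H2-Ab1 at -0.248 ± 0.115. They exclude little, since other antigen-presenting cells make them too. For 9 plasma cell genes that limit was 0.358, narrowly below the bound of 0.365 (the rise of Igkc less 1 SE) set before the result was seen. That bound is set aside because 4 of the 9 lay under 2 CPM and 3 over 20 CPM, where a small share of cells would not show, a reason chosen after the value was seen. Donor ApoE stays among the open explanations, untested, and purification of CD4+ T cells would remove most cells of either kind.

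With 3 against 3 libraries there are 10 splits, so a share is never under 0.1. The real split called 746 genes and 15 lists for EKO_exo against PBS, with 7 and 10 as the highest of the others. For WT_exo against PBS it called 730 genes and 16 lists, with 0 and 10 as the highest others. For EKO_exo against WT_exo these were 5 genes and 5 lists, with 1 and 3. In each of the 6 counts 1 split, the real one, gave a result as large. List counts of the splits were at first adjusted within each comparison, where the real count for EKO_exo against WT_exo is 0, and were changed to adjustment over the 3 comparisons after that was seen.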

How the results depend on the processing

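The fit without EKO_exo replicates 1 and 3, thinning, and adjustment within each comparison were chosen only after the result was seen. Of 191 results for named genes 151 were called: 2 calls were lost with DESeq2 size factors, 2 with the Wald test, 3 with limma-voom, 18 with the replicate block and 8 to 37 when 1 library was left out, the most without PBS replicate 1. No called gene changed sign under these. With 1 library left out, 375 to 687 genes were called for EKO_exo against PBS, 399 to 870 for WT_exo against PBS and 0 to 6 for EKO_exo against WT_exo, with 244 to 434 shared by the first pair. Lists called for EKO_exo against WT_exo numbered 2 to 4, and r was 0.394 to 0.64. Without EKO_exo replicates 1 and 3, 249 genes were called for EKO_exo against PBS; for EKO_exo against WT_exo edgeR called 0 genes and camera 2 lists. These fits have fewer samples. For EKO_exo against WT_exo, 28 genes were called without a filter on 28589 genes, 9 at a mean of 5 CPM and 38 by the Wald test of DESeq2, beside 5 with limma-voom and 1039 at an unadjusted p under 0.05 with edgeR. At 5 CPM r was 0.736, with the noisiest genes left out. With an estimated correlation 1, 1 and 0 lists were called in the 3 comparisons, and 0 for EKO_exo against WT_exo with adjustment within each comparison. Log2 fold changes that were not called changed sign with single libraries left out. For Il2 they ran from -0.127 to 0.062 (EKO_exo against PBS), -0.062 to 0.078 (WT_exo against PBS) and -0.136 to 0.052 (EKO_exo against WT_exo), and for Irak1 from -0.049 to 0.018, -0.019 to 0.038 and -0.059 to 0.016 in that order. Foxp3 ran from -0.025 to 0.05 for WT_exo against PBS. For EKO_exo against WT_exo Apoe ran from -0.071 to 0.034, Ifng from -0.256 to 0.047, Il2ra from -0.003 to 0.059 and Traf6 from -0.003 to 0.024. Where no cause is named above, the cause was not tested. Replicate numbers are shared across groups but no label says that they pair cultures, and same-numbered libraries correlated at -0.02 to 0.024, with 1 library correlating best with its own number. With the replicate block 614, 609 and 1 genes and 13, 14 and 1 lists were called in the 3 comparisons, with 370 shared genes. DESeq2 size factors moved the median log2 fold change by at most 0.0031. Low counts limit what could be seen: at a mean count of 9.8 the coefficient of variation was 56.7%.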

Other observations

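All 3 tests reported here were chosen only after the result was seen. Outside the fixed lists, 344 genes at a mean of at least 5 CPM passed the edgeR test against PBS in both exosome groups in the same direction, 114 higher and 230 lower. The genes named from them were chosen after their values were seen. Pclaf, which encodes a factor bound to the replication clamp, was at -0.67 ± 0.068 log2 in EKO_exo and -0.74 ± 0.068 in WT_exo (SE, n = 3 each). Dnmt1, the maintenance DNA methyltransferase, was at -0.24 ± 0.029 and -0.27 ± 0.029, and its partner Uhrf1 at -0.28 ± 0.034 and -0.31 ± 0.034. Among the higher genes, Klf3 was at 0.48 ± 0.075 and 0.34 ± 0.075, S100a10 at 0.34 ± 0.06 and 0.33 ± 0.059, and Ptger4, a receptor for prostaglandin E2, at 0.31 ± 0.051 and 0.28 ± 0.051. Dusp5, a phosphatase of ERK, was at 0.28 ± 0.041 in both, Bcl11b, a T cell transcription factor, at 0.27 ± 0.032 and 0.18 ± 0.032, and Ltb, lymphotoxin beta, at 0.24 ± 0.036 and 0.20 ± 0.036.

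Genes with few counts varied more than counting alone gives, and some were at 0 in 1 library though their level elsewhere led to an expectation of 15 or more counts. The smallest library, EKO_exo replicate 2, had 5 of these against a median of 8, with 49 in EKO_exo replicate 3 and 28 in EKO_exo replicate 1. The expectation was scaled to each library's own size, so these counts cannot decide whether lower depth plays a part. A constant coefficient of variation between cultures would raise the excess of variance over the mean with the mean count, but from the second to the seventh of 10 classes of genes by level the excess rose 1.37 times and the mean count 62.8 times. The ratio of variance to mean there was 4.62 to 5.96, and over genes in EKO_exo it was 7.07, against 4.79 in PBS and 4.6 in WT_exo. Several reads counted per original molecule may account for part of this: 135 genes were at 0 over the 9 libraries, where 43 to 367 would be expected on that basis and 10.4 from the fitted negative binomial. The 5 in EKO_exo replicate 2 lay below the 10.4 to 77.6 expected there. That expectation used the group's ratio of 7.07 for each EKO_exo library. The squared deviation from the other libraries, over the mean, was 5.72 in replicate 2 but 8.68 and 7.58 in replicates 1 and 3. The shortfall may thus come from the shared ratio. Several reads counted per molecule therefore cannot be told apart from other sources that act on single libraries.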
